A study of Mus musculus with 23 samples.

How the data were processed

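Gene expression was measured in hindlimb muscle of female C57BL/6J mice aged 77 days, with 1 Affymetrix array per sample and 23 arrays in 5 groups. Per the labels' protocols, the tissue was snap-frozen, RNA was extracted with Trizol and cleaned on RNeasy columns, and its quality was read by absorbance and on a Bioanalyzer. Biotin-labelled cRNA was hybridised. The deposited values are on the log2 scale, between 2.49 and 14.2. Per the submitters' processing notes, RMA and MAS5 were used; which of them made the table, their versions, and whether all 23 arrays were normalized together are not given in the sources used here. No background correction or normalization was added to the deposited log2 values.

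The groups were taken from the sample titles, which match the source names and the series design. The free-text descriptions of the ground enclosure samples describe flown animals, and those of the spaceflight samples describe enclosure housing. The titles, the source names and the series design stand together against these descriptions, and the descriptions were not used. If the descriptions were right, every sign of the flight comparison would turn, and the differences between the flight effect and a calf effect would turn into tests of their sum. The fits were therefore repeated with the 2 flight groups exchanged, an alternative added after seeing the data. The labels give replicate numbers but do not say that each replicate is a separate animal, so p-values measure the spread between these samples. Scan dates, array batches and the time between landing and dissection are not given in the sources used here, so no batch could be tested.

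Of the 22690 probe sets, 64 control probe sets were left out. In the platform annotation table, which can be old, 20380 of the other 22626 probe sets have 1 gene symbol, 691 have several and 1555 are unnamed. The symbols were compared with RefSeq names through the Entrez identifier, which led to 0 changes, and no coordinates are printed because the sources name no genome build. Each of 12393 genes was represented by its probe set with the highest mean log2 value over the 23 arrays, a choice that matters for 4956 genes with several probe sets. Genes were tested where the log2 value lay above 5.83, the 40th percentile of the table, on at least 4 arrays, which kept 9133 genes and left out 3260. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.09 in each of the 4 comparisons of groups. Array range (the 75th minus the 25th percentile of the log2 values) was 2.75 to 2.91 on the flight experiment's arrays and 2.20 to 2.46 on the calf arrays, so levels were not compared between the flight and calf experiments.

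Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided moderated test) in R 4.3.3, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 9133 genes. The 8 gastrocnemius arrays were fitted on their own, the 15 calf arrays shared 1 estimate of the spread, and differences between the flight effect and a calf effect were tested over all 23 arrays with 5 group means, each effect taken within its own experiment. For 30 gene lists of pathways, fibre types, stress responses and cell types, camera with a preset correlation of 0.01 was the main test, with an estimated correlation and fry beside it, adjusted over the 29 lists with enough tested genes. The erythroid list had 1 tested gene, so no list test was run on it. Overlaps were tested with Fisher's exact test, two-sided, against all genes tested. That test takes genes as independent replicates, which they are not, so its p-values only describe the overlaps.

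The groups, lists, tests, thresholds and most alternatives were chosen before the data were examined, as was the rule for naming genes. In each comparison of groups, the rule took the 5 called genes with the largest increase and the 5 with the largest decrease among genes whose groups did not overlap, and up to 4 called members of a list past camera (up to 2 of other lists). It also took 20 fixed genes whether called or not, and for each difference of effects the 5 largest called values in each direction. Trim63 and Mstn, which belong to the fixed genes, were not analysed here. Genes named only because 2 comparisons shared them were chosen after their values were seen, whereas second marker lists of adipocytes and Schwann cells were chosen after the first lists' results and before their own values were seen.

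The alternatives were no filter on low values, a filter at the 60th percentile, each probe set tested on its own, the mean of a gene's probe sets, quantile normalization within each experiment, arrays centred on their median over the tested genes, an eBayes trend with robust estimation, array weights, a change of at least 1.5-fold, an adjusted p under 0.01, other sets of arrays in the fit, and leaving out each array in turn. Leaving out suspension replicates 8 and 9 together, array range as a covariate, centring on the median of all probe sets, quantile normalization over the tested genes alone, and the gene lists without suspension replicate 8 or under other scaling were added after seeing the data, as were the other probe sets of named genes. The fits were tested on simulated data in which 200 of 9133 genes were changed. The simulated noise was independent between genes and had the same spread in every group. The flight fit recovered 84% of genes changed 1.5-fold and 99% of those changed 2-fold, and the 3 calf comparisons recovered 92% to 94% and 100%. The tests of differences between effects recovered 65% and 66% of the genes changed 1.5-fold, and 96% and 95% of those changed 2-fold. Between 5 and 13 unchanged genes were called per comparison. The real calf arrays spread unequally between groups and share trends across genes, so these shares can overstate what was recovered there. Plots were drawn in Python 3.11.15 with matplotlib 3.10.9.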

Results

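Expression was profiled in gastrocnemius muscle of mice flown in space for 11 days and 19 hours (n = 4) and of mice kept for the same time on the ground in the animal enclosure module (ground AEM, n = 4). A second experiment profiled calf muscle of untreated controls (n = 5), of mice whose hindlimbs were unloaded by tail suspension for 12 days (n = 5), and of mice suspended for 12 days and then returned to weight bearing for 3.5 hours (reloaded, n = 5). Median log2 signal per array lay between 6.15 and 6.23 in the flight experiment and between 6.28 and 6.39 in the calf experiment. Within a group, the lowest correlation between arrays was 0.988 in the flight experiment and 0.969 in the calf experiment, and no array duplicated another. Suspension replicate 8 had a median correlation of 0.975 with the rest of its group, where each other array of the 23 reached at least 0.983. Group names follow the sample titles; the free-text descriptions of the spaceflight and ground AEM samples are exchanged between the groups, and if those were right every sign of the flight comparison would turn. Differences between the flight effect and a calf effect would then change in size and in the genes called as well.

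The first comparison asks what spaceflight did to gene expression in gastrocnemius. In the 4 spaceflight arrays, the metallothionein Mt2, a metal-binding stress protein, reached a mean log2 signal of 12.10 ± 0.29 (SD, n = 4) against 8.73 ± 1.22 in ground AEM (n = 4). This is a log2 increase of 3.37 ± 0.43 (SE, limma adjusted p = 0.000596). Its neighbour in function Mt1 rose by 2.25 ± 0.36 (adjusted p = 0.00288), and Ddit4, an inhibitor of mTOR signalling, rose by 2.82 ± 0.54 (adjusted p = 0.00884). The transcription factor Cebpd rose by 1.74 ± 0.17 (adjusted p = 0.000109) and the lipid droplet protein Cidec by 1.67 ± 0.17 (adjusted p = 0.00019). Among genes whose groups did not overlap, the largest decreases were in the apelin receptor Aplnr (log2 change -1.43 ± 0.13, adjusted p = 9.1e-05) and in Ppargc1a, a coactivator of mitochondrial biogenesis, whose mean fell from 9.46 ± 0.34 to 8.23 ± 0.14 (log2 change -1.23 ± 0.14, adjusted p = 0.000322). The endothelial transcription factor Sox18 fell by 1.12, Sh3d19 by 1.08 and the differentiation inhibitor Id1 by 1.07 on the log2 scale. Second probe sets, at lower levels, did not pass for Cebpd (0.06), Aplnr (-0.26) and Sh3d19 (-0.10). In all, limma called 515 of 9133 genes, 290 higher and 225 lower in spaceflight, of which 32 rose and 6 fell at least 2-fold; with any single array left out the count lay between 283 and 491.

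Genes that respond to glucocorticoids rose together in spaceflight. Of 16 tested members, 11 rose, 0 fell and 5 did not pass (14 rose when adjusted over the list alone). Their median log2 difference was 0.64, with adjusted p = 2.37e-16 in camera, and adjusted p = 0.0549 with an estimated correlation. Besides Cebpd, Mt2 and Ddit4, the members included Foxo1, a transcription factor of the atrophy programme (1.37 ± 0.16, adjusted p = 0.000373), and Fkbp5, a chaperone of the glucocorticoid receptor (0.84 ± 0.11, adjusted p = 0.000625). Ground AEM replicate 2 had the highest value of its group in 11 of the 16 genes. Its Ddit4 stood at 10.68 and its Mt2 at 10.51, below the lowest spaceflight values of 10.79 and 11.79. Of 11 growth arrest and p53 target genes, 6 rose and 0 fell (8 rose and 1 fell when adjusted over the list alone). Their median was 0.77 (camera adjusted p = 1.21e-07, and adjusted p = 0.0555 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 1.43 ± 0.12 (adjusted p = 9.1e-05), Btg2 by 1.65, Trp53inp1 by 1.16 and Sesn1 by 0.77. The other probe set of Trp53inp1, at a lower level, differed by only 0.24. Circadian clock genes had 4 of 14 members higher and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.0251, and adjusted p = 0.518 with an estimated correlation). These were Per1 (1.59), Nfil3 (1.02), Arntl (0.44) and Nr1d1 (0.37), and the list's call also ended with the mean of each gene's probe sets (adjusted p = 0.0979). Per1 is also a member of the glucocorticoid list.

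**Figure D1:**
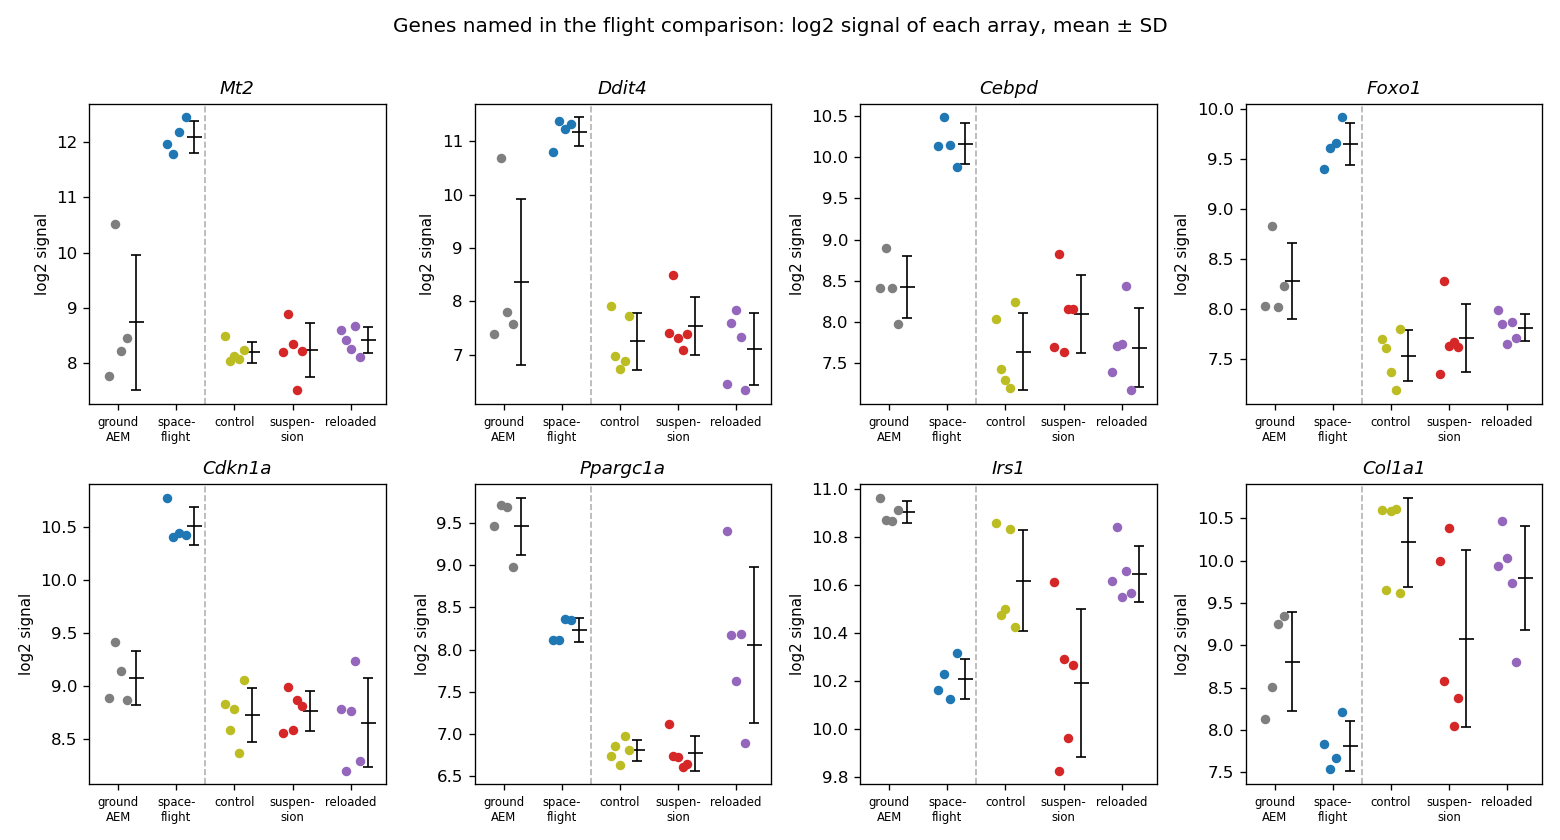
Log2 signal of 8 genes named in the flight comparison, 1 point per array, with the mean ± SD of each group and a dashed line between the flight and calf experiments. Every spaceflight array lay above every ground AEM array for Mt2 (lowest 11.79 against highest 10.51) and below them for Ppargc1a (highest 8.37 against lowest 8.98), while 1 ground AEM array stood at 10.68 for Ddit4.

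Transcripts of several genes of insulin and IGF1 signalling changed, while signalling activity was not measured. Foxo1, given above with the glucocorticoid-responsive genes, is a member of this list too. Of 20 tested members, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.00779, and adjusted p = 0.176 with an estimated correlation). The insulin receptor substrate Irs1 fell from 10.91 ± 0.05 to 10.21 ± 0.08 (SD, n = 4 each; log2 change -0.70 ± 0.07, limma adjusted p = 0.000217), while the PI3-kinase subunit Pik3r1 rose by 0.62 ± 0.12 and the translation repressor Eif4ebp1 by 0.52 ± 0.08. Igf1 differed by -0.07 ± 0.11 (adjusted p = 0.787). Immediate-early genes, which answer stimuli within minutes, had 7 of 22 members higher and 2 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.000153, and adjusted p = 0.415 with an estimated correlation). Among them Zfp36 rose by 1.58 and Ier5 by 0.72, and Klf2 fell by 0.56 on the log2 scale. Other probe sets of Ier5, at lower levels, differed by -0.05 and -0.15. The immediate-early list's median of 0.40 was 0.14 with array range as a covariate. The inhibitor of NF-kappa-B, Nfkbia, rose by 0.87, the 1 called gene among 11 tested cytokine and chemokine pathway genes.

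Genes of the extracellular matrix were lower in spaceflight. Of 26 tested, 0 rose and 7 fell (11 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 2.5e-06, and adjusted p = 0.536 with an estimated correlation). Collagen genes Col1a1 (log2 change -0.99 ± 0.23, adjusted p = 0.0256), Col3a1 (-0.61 ± 0.15, adjusted p = 0.0376), Col5a2 (-0.50) and Col6a2 (-0.48) fell, as did the collagen chaperone Serpinh1 (-0.53). Tendon and connective tissue markers had 1 of 12 lower, Tnc (-0.52), with a median of -0.28 (camera adjusted p = 0.0389, and adjusted p = 0.718 with an estimated correlation). Fatty acid uptake and oxidation genes had 1 of 24 higher and 2 lower (1 and 5 adjusted over the list alone; camera adjusted p = 0.00152, and adjusted p = 0.536 with an estimated correlation). The uncoupling protein Ucp3 rose by 0.80, and Ppargc1a and the lipid-sensing receptor Ppara (-0.82) fell. Oxidative phosphorylation genes had a median of -0.10 over 58 members (camera adjusted p = 0.000216, and adjusted p = 0.424 with an estimated correlation). Of these only Ndufb5 (-0.30) fell, and 0 passed when adjusted over the list alone. Ribosome biogenesis genes had a median of 0.12 with 0 of 19 called (camera adjusted p = 0.00655, and adjusted p = 0.313 with an estimated correlation).

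Adipocyte markers rose. Of 8 tested, 5 rose and 0 fell (6 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 1.02e-07, and adjusted p = 0.0555 with an estimated correlation). The hormone adiponectin, Adipoq, rose by 1.44 ± 0.12 (limma adjusted p = 9.1e-05), resistin, Retn, by 1.05, the lipase Lipe by 0.63, and Cidec as above. Fabp4 (0.27), Scd1 (0.30) and Car3 (-0.11) did not pass. Markers of macrophages, Schwann cells and skin had 0 called genes, with camera adjusted p of 0.577, 0.577 and 0.535, and endothelial markers had 1 called of 13, Kdr (-0.32; list adjusted p = 0.595). The endothelial median was 0.03 although camera ranked the list as lower. The 1 tested erythroid gene, Alas2, fell by 0.28 on the log2 scale.

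Few contractile and proteasome genes were called in flight, and the ubiquitin ligase Fbxo32 (atrogin-1) depends on the probe set read. Myosin heavy chains Myh7 (0.19), Myh2 (-0.22), Myh1 (-0.05) and Myh4 (-0.02) did not pass, and 0 of 14 fast fibre genes were called. Among 13 slow fibre genes, sarcolipin, Sln, rose by 1.36 ± 0.27 (adjusted p = 0.0102) and 2 fell, including Myl2 (-0.42). The other probe set of Sln, at a lower level, differed by -0.09. Fbxo32 differed by 0.20 ± 0.12 in its chosen probe set (adjusted p = 0.381). Its other probe set rose by 0.72 ± 0.12 (limma adjusted p = 0.00324 over all probe sets), and the mean of both rose by 0.46 (adjusted p = 0.0282). Ube2j1 rose by 0.40 and the proteasome subunits Psma4 (-0.36) and Psmd7 (-0.35) fell, with 0 of the other 29 subunits called. In the autophagy list Ulk1 rose by 0.33 and Wipi1 fell by 0.52, in the denervation list Myog rose by 0.84 and Musk by 0.54, and in the stretch list Ccn1 rose by 0.83 and Ccn2 fell by 0.55. None of these 3 lists passed camera, and the stretch list had a median of -0.01 although camera ranked it as higher. Hsp90b1 of the unfolded protein response fell by 0.46, in a list whose median was 0.03 although camera ranked it as lower (adjusted p = 0.891). The cell cycle gene Ccnd1 (-0.41) and Id3 (-0.65) also fell, whereas Hspa1b (-0.41), Ankrd1 (0.51) and Ankrd2 (-0.17) did not pass. Rrad lay below the filter, and its log2 change without the filter was -0.55 (adjusted p = 0.00576).

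In the flight comparison, 480 of the 515 called genes had groups that did not overlap, as did 12.4% of all tested genes against 2.86% by chance; the share of higher genes depends on scaling, with 254 higher and 247 lower when arrays were centred on the median of the tested genes, and 352 and 174 when centred on that of all probe sets. The calls of 18 of 55 named genes ended when some single array was left out: Col1a1, Col3a1, Col5a2, Col6a2, Myl2, Musk, Myog, Arntl, Nr1d1, Tnc, Kdr, Ndufb5, Psma4, Psmd7, Ulk1, Ccn2, Ccnd1 and Alas2; those of Mt1 (adjusted p = 0.0609) and Ddit4 (adjusted p = 0.102) ended under eBayes with trend and robust estimation.

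The second comparison asks what unloading without flight did. In the 5 suspension arrays, the ketone body enzyme Bdh1 fell from 8.60 ± 0.04 to 7.22 ± 0.34 (SD, n = 5 each; log2 change -1.38 ± 0.15, limma adjusted p = 3.66e-05), and the fatty acid binding protein of muscle, Fabp3, fell by 1.03 ± 0.14 on the log2 scale (adjusted p = 0.000805). The small heat shock protein Hspb7 (-0.89), the TWEAK receptor Tnfrsf12a (-0.81) and Pdlim1 (-0.79 ± 0.08, adjusted p = 2.47e-05) also fell. Myelin basic protein, Mbp, rose from 8.92 ± 0.36 to 10.79 ± 0.29 (1.87 ± 0.38, adjusted p = 0.0287), fatty acid synthase, Fasn, by 1.62 ± 0.32 (adjusted p = 0.0244), Cyp2e1 by 1.10 ± 0.14 (adjusted p = 0.000442), transketolase, Tkt, by 0.96 and Ndrg1 by 0.77. In all, limma called 34 genes, 12 higher and 22 lower.

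Lists of oxidative, slow fibre and load-dependent genes were lower as groups in suspended muscle, mostly through small changes of many members, and with an estimated correlation 0 of the 29 lists passed. Of 24 fatty acid genes, 1 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 3.85e-16, and adjusted p = 0.0768 with an estimated correlation). Of 13 slow fibre genes, 3 fell (7 adjusted over the list alone; camera adjusted p = 1.75e-13, and adjusted p = 0.0843 with an estimated correlation). These were the calsequestrin Casq2 (-0.64), the slow myosin light chain Myl3 (-0.47) and Myoz2 (-0.56). Oxidative phosphorylation genes had a median of -0.11 with 0 of 58 called (camera adjusted p = 2.36e-12, and adjusted p = 0.166 with an estimated correlation). Suspension replicate 8 lay lower than the other 4 suspension arrays in these genes, by a median of -0.205 with 51 of 58 members below; without it the list's median was -0.08 and camera's adjusted p 3.33e-08. Stretch-responsive sarcomere genes had a median of -0.40 (camera adjusted p = 6.6e-10, and adjusted p = 0.123 with an estimated correlation). The Z-disc protein Csrp3 (-0.76) was the 1 member called of 14, and 9 were lower when adjusted over the list alone. Without suspension replicates 8 and 9 the medians were -0.23 for stretch-responsive and -0.06 for oxidative phosphorylation genes, with both lists still past camera. Heat shock proteins had 2 of 23 lower, Hspb7 and Cryab (-0.44), and 8 adjusted over the list alone (camera adjusted p = 2.33e-11, and adjusted p = 0.123 with an estimated correlation). That array deviated by -0.25 in heat shock genes, whose median without it was -0.18 (camera adjusted p = 2.65e-09).

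Extracellular matrix genes had a median of -0.24 with 0 of 26 called and 9 lower when adjusted over the list alone (camera adjusted p = 2.33e-11, and adjusted p = 0.123 with an estimated correlation). Col1a1 differed by -1.13 ± 0.38 and Col3a1 by -0.58 ± 0.18, with adjusted p of 0.311 and 0.259. Without suspension replicates 8 and 9 the extracellular matrix median was -0.16 and that of tendon markers, -0.26 in all arrays, was -0.13, with both lists still past camera. Tendon markers had Chad (-0.57) called of 12 (camera adjusted p = 3.81e-07, and adjusted p = 0.123 with an estimated correlation), and the immediate-early list had Klf4 (-0.57) called of 22 (camera adjusted p = 0.00644, and adjusted p = 0.328 with an estimated correlation). Proteasome subunits had a median of -0.13 and metallothionein and antioxidant genes -0.08, with 0 called in either list (camera adjusted p = 6.17e-05 and 0.0087, and adjusted p = 0.424 and 0.328 with an estimated correlation). Suspension replicate 8 deviated by -0.208 and -0.205 in these 2 lists, and without it both calls ended, with medians of -0.05 and -0.11 and camera adjusted p = 0.0554 each. Schwann cell markers were higher, with Mbp called of 6 and all 6 higher when adjusted over the list alone. Their median was 0.35 (camera adjusted p = 1.44e-09, and adjusted p = 0.0768 with an estimated correlation). Adipocyte markers had a median of 0.39 with 0 of 8 called and 5 higher when adjusted over the list alone (camera adjusted p = 9.16e-06, and adjusted p = 0.159 with an estimated correlation). A second adipocyte list did not repeat this clearly. Its 11 members above the level filter had a median of 0.06, and 12 of all 15 were higher. Npr3 was called lower (-0.69) and Pck1, below the filter, higher (0.54), each with adjusted p = 0.0492 in limma without the filter. Suspension replicate 8 deviated by 0.221 in Schwann cell and 0.287 in adipocyte markers. Of the fixed genes, Mt2 (0.04), Mt1 (0.09), Cdkn1a (0.04), Foxo1 (0.18), Fbxo32 (-0.02), Ppargc1a (-0.04), Myh7 (-0.24) and Ankrd1 (-0.60) did not pass, nor did Myh2 (-0.35, adjusted p = 0.057) and Ankrd2 (-0.76, adjusted p = 0.0695).

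In the suspension comparison, the groups of all 34 called genes did not overlap, as was so for 2.04% of all tested genes against 0.794% by chance; a split of these arrays across the groups called 901. Without suspension replicates 8 and 9 together 7 genes were called, and the calls of Mbp, Fasn, Myl3, Myoz2, Cryab, Klf4, Id1 and Chad ended when some single array was left out; those of Mbp (adjusted p = 0.173) and Fasn (adjusted p = 0.161) also ended under eBayes with trend and robust estimation, and that of Pdlim1 (-0.26) as the mean of its probe sets.

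The third comparison asks how suspended muscle answered 3.5 hours of weight bearing. The inducible heat shock proteins Hspa1b and Hspa1a, near-identical gene copies that probes hardly tell apart, rose by 3.01 ± 0.26 (limma adjusted p = 8.57e-07) and 2.75 ± 0.28 (adjusted p = 5.3e-06) on the log2 scale. Hspa1b went from 6.80 ± 0.20 in suspension (SD, n = 5) to 9.81 ± 0.84 in reloaded muscle (n = 5). The stress transcription factor Atf3 rose by 2.23 ± 0.22 (adjusted p = 4.14e-06), the actin-binding repair protein Xirp1 by 2.09 ± 0.21 (adjusted p = 5.83e-06) and the cardiac ankyrin repeat protein Ankrd1 by 2.04 ± 0.22 (adjusted p = 1.19e-05). Of 53 called genes, 50 rose and 3 fell, among the latter the clock repressor Bhlhe40 (-0.52) and Aox1 (-0.47).

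Stretch-responsive sarcomere genes rose, with 9 of 14 higher and 0 lower (10 adjusted over the list alone). Their median was 0.89 (camera adjusted p = 1.94e-31, and adjusted p = 0.0099 with an estimated correlation). Csrp3 rose by 1.60 ± 0.13 (adjusted p = 6.54e-07), the actin regulator Enah by 1.27 and Ankrd2 by 1.24. Heat shock proteins had 8 of 23 higher (14 adjusted over the list alone; camera adjusted p = 3.31e-26, and adjusted p = 0.0225 with an estimated correlation). They included Hspb1 (0.80) and Dnaja4 (0.73). Immediate-early genes had 8 of 22 higher (10 adjusted over the list alone), including Jun (1.17), Btg2 (1.01) and Ier5 (0.94). That list had camera adjusted p = 2.3e-15, and adjusted p = 0.0099 with an estimated correlation. The unfolded protein response list passed both tests as well (adjusted p = 0.000186, and adjusted p = 0.0416 with an estimated correlation). Atf3, also an immediate-early gene, was its 1 called member of 15, and 3 were higher when adjusted over the list alone. Ppargc1a rose by 1.29 ± 0.27 (adjusted p = 0.0261), the antioxidant enzyme Srxn1 by 1.02 and the myogenic factor Myf6 by 0.62.

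**Figure D2:**
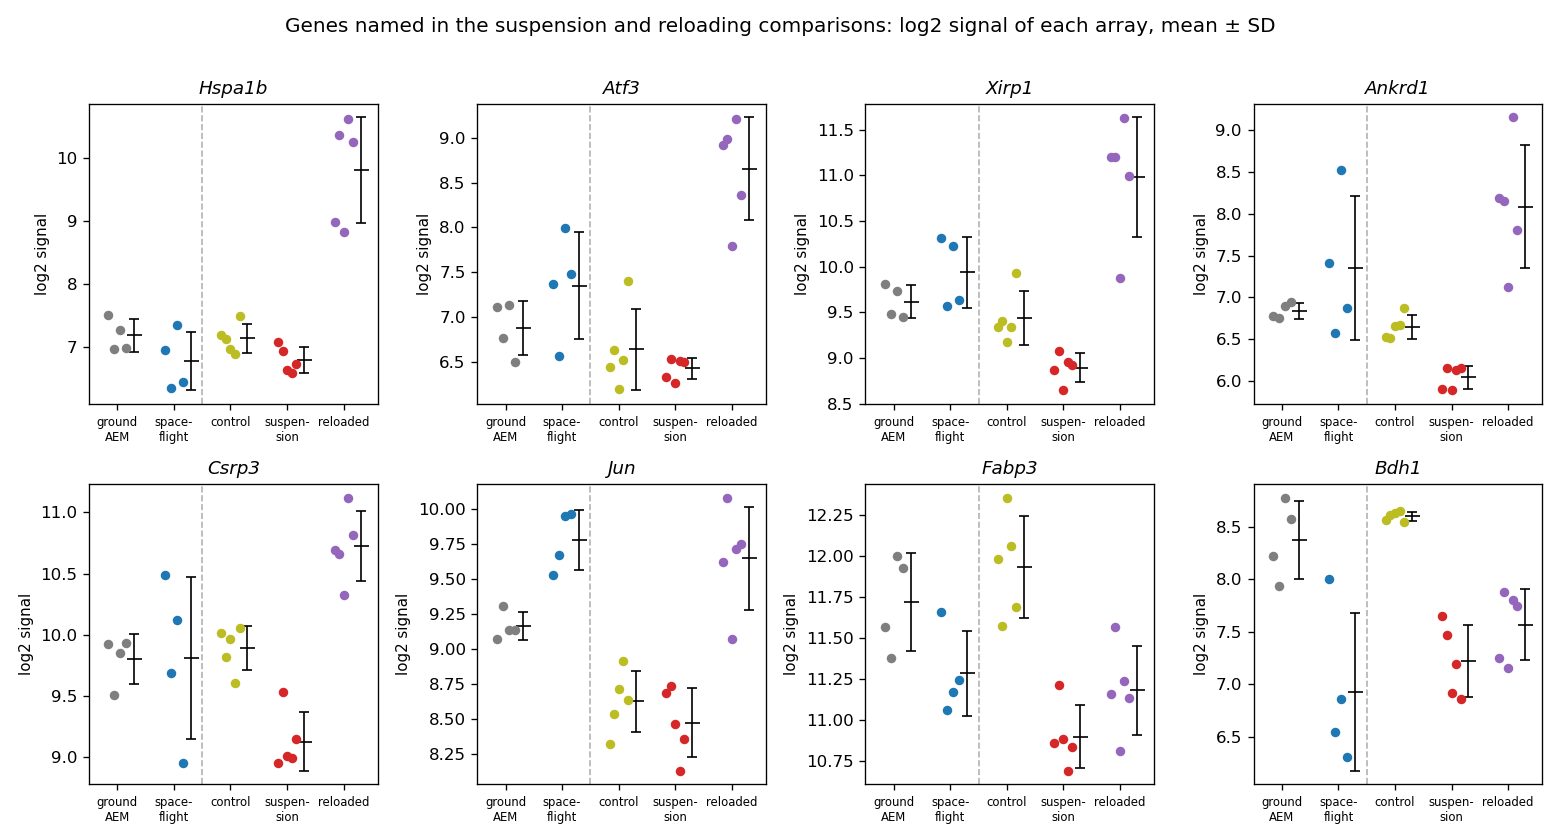
Log2 signal of 8 genes named in the suspension and reloading comparisons, 1 point per array, with the mean ± SD of each group and a dashed line between the flight and calf experiments. The 5 reloaded arrays lay between 8.82 and 10.61 for Hspa1b and the 5 suspension arrays between 6.60 and 7.08, while Bdh1 lay between 8.55 and 8.64 in control arrays and between 6.86 and 7.65 in suspension arrays.

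Several lists that were low in suspension had positive medians after reloading, but their camera calls ended with an estimated correlation. These were the extracellular matrix (0.16, adjusted p = 2.1e-06, and adjusted p = 0.451 with an estimated correlation), tendon markers (0.26, adjusted p = 2.1e-06, and adjusted p = 0.124 with an estimated correlation), where Thbs4 rose by 0.47, and slow fibre genes (0.15, adjusted p = 0.00366, and adjusted p = 0.555 with an estimated correlation). Without suspension replicates 8 and 9 the medians of the extracellular matrix, tendon and heat shock lists were 0.09, 0.13 and 0.21, against 0.16, 0.26 and 0.37, and all 3 still passed camera. Metallothionein and antioxidant genes (0.02) and proteasome subunits (0.04) had camera adjusted p of 0.0116 and 0.0345, and adjusted p of 0.451 and 0.782 with an estimated correlation. Without suspension replicate 8 both calls ended (camera adjusted p = 0.0636 and 0.937), and the proteasome list turned to -0.0107, and to -0.0271 without replicates 8 and 9 (adjusted p = 0.549). Schwann cell markers (-0.19) and adipocyte markers (-0.24) had camera adjusted p of 0.00918 and 0.0245, and adjusted p of 0.451 and 0.555 with an estimated correlation, with 0 genes called in either list. The adipocyte call ended without suspension replicate 8 (median -0.20, adjusted p = 0.08) but not without replicates 8 and 9 together (-0.22, adjusted p = 0.00813). The Schwann call ended without replicates 8 and 9 (adjusted p = 0.167). Across genes, the reloading effect and the suspension effect had r = -0.597 with shared suspension arrays, against -0.499 in simulations without effects. Their covariance was -0.0119 against -0.00509 simulated, and r had a median of -0.235 with the suspension arrays split between the 2 effects (range -0.361 to 0.184). The simulations gave all 3 calf groups the same spread per gene. The suspension arrays spread more, with an SD around the group mean of 0.132 to 0.229, against 0.108 to 0.138 on the other calf arrays. A wider spread of the shared arrays alone makes r and the covariance more negative, so the simulations cannot decide whether reloading reversed suspension.

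In the reloading comparison, 42 of the 53 called genes had groups that did not overlap, as did 1.46% of all tested genes against 0.794% by chance. The calls of Bhlhe40, Aox1, Ppargc1a and Myf6 ended when some single array was left out.

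The comparison of reloaded muscle with control gives the net difference after suspension and reloading. Hspa1b was higher by 2.67 ± 0.26 (limma adjusted p = 1.39e-05), Hspa1a by 2.45, Atf3 by 2.02, the amino acid transporter Slc38a2 by 1.45 ± 0.16 (adjusted p = 5.22e-05) and Ankrd1 by 1.44. Bdh1 (-1.03 ± 0.15, adjusted p = 0.00101), Fabp3 (-0.75), the mitochondrial enzyme Idh2 (-0.63) and Ldhb (-0.58) were lower. In all, 29 genes were called, 24 higher and 5 lower, and 0 of the 29 lists passed with an estimated correlation.

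Stretch-responsive genes had 5 of 14 higher than in control (9 adjusted over the list alone), among them Xirp1 (1.54), Enah (0.90) and Csrp3 (0.83). Their median was 0.42 (camera adjusted p = 1.2e-17, and adjusted p = 0.0615 with an estimated correlation). Immediate-early genes had 3 of 22 higher (7 adjusted over the list alone), including Jun (1.02) and Ier5 (0.87), with camera adjusted p = 5.54e-10, and adjusted p = 0.0615 with an estimated correlation. Heat shock proteins had 4 of 23 higher (6 adjusted over the list alone), including Dnajb4 (0.66) and Hspb1 (0.53), with camera adjusted p = 1.13e-07, and adjusted p = 0.261 with an estimated correlation. The unfolded protein response list had a median of 0.06 (camera adjusted p = 0.00309, and adjusted p = 0.136 with an estimated correlation). Fatty acid genes had a median of -0.25 against control, in arrays that the suspension comparison shares (camera adjusted p = 3.21e-12, and adjusted p = 0.125 with an estimated correlation). Fabp3 was the 1 called of 24, and 16 were lower and 1 higher when adjusted over the list alone. Slow fibre genes (-0.20) and oxidative phosphorylation genes (-0.11) had camera adjusted p of 4.05e-07 and 3.25e-08, and adjusted p of 0.245 and 0.289 with an estimated correlation. Medians of Schwann cell (0.21), adipocyte (0.16) and macrophage markers (0.06) were positive and that of endothelial markers (-0.12) negative, with 0 genes called. Camera gave them adjusted p of 0.0002, 0.0362, 0.00549 and 0.0242, and adjusted p of 0.245, 0.47, 0.339 and 0.261 with an estimated correlation. Ppargc1a differed by 1.25 ± 0.27 (adjusted p = 0.056), although 4 other probe sets of Ppargc1a passed over all probe sets, with 0.99 to 1.21 (adjusted p = 0.0119 to 0.0349). Another probe set of Foxo1 passed too (0.62, adjusted p = 0.0461), where the chosen one differed by 0.28, and Srxn1 rose by 0.75 (adjusted p = 0.049).

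Of the 29 genes called between reloaded and control muscle, 24 had groups that did not overlap, as did 2.64% of all tested genes against 0.794% by chance. The count rose to 53 with the 2 groups fitted alone and to 88 with array weights, and the calls of Fabp3, Dnajb4, Hspb1 and Srxn1 ended when some single array was left out. The shared estimate of the spread takes in the suspension arrays, which spread more. The counts of called genes therefore do not rank the calf comparisons by the size of their effects.

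**Figure D3:**
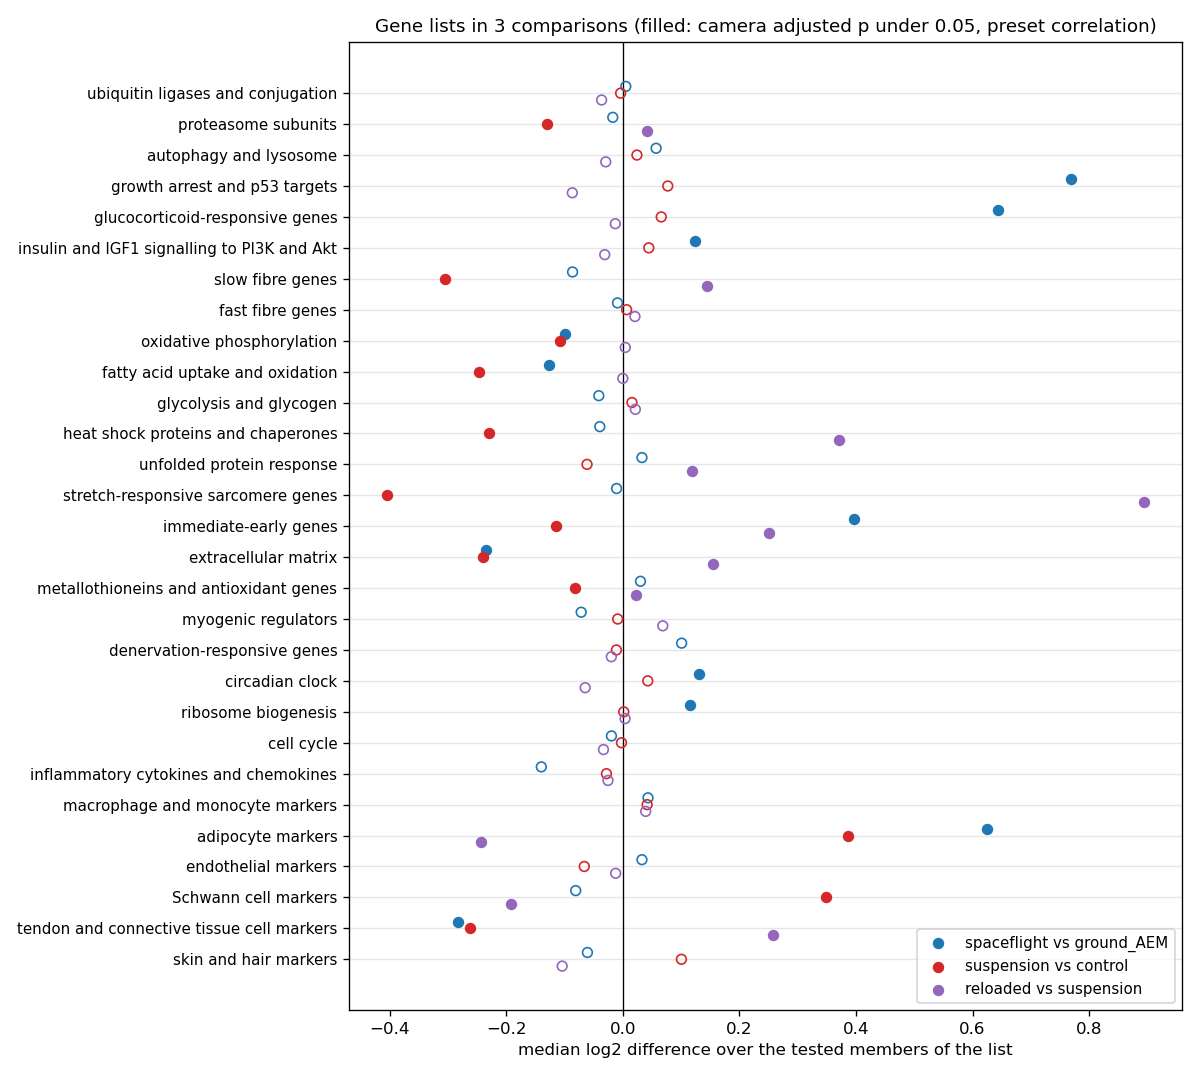
Median log2 difference of each gene list in the flight, suspension and reloading comparisons, with 1 point per list and comparison, filled where camera's adjusted p with the preset correlation lay under 0.05. Glucocorticoid-responsive genes had a median of 0.64 in flight and 0.07 in suspension, and stretch-responsive genes -0.01 in flight, -0.40 in suspension and 0.89 after reloading.

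The remaining comparisons ask how far flight resembled unloading on the ground. Flight and suspension shared 6 genes that rose in both (Fasn, Cyp2e1, Tkt, Gpt2, Tfcp2l1 and Art3) against 0.381 expected from independent lists (Fisher's exact test, two-sided, p = 7.66e-07). They shared 6 that fell in both (Bdh1, Id1, Klf4, Pdlim1, Nup133 and Rmdn1) against 0.542 expected (Fisher's exact p = 1.12e-05), and 0 genes were called in opposite directions (0.699 and 0.296 expected). Fisher's test takes genes as independent, and genes that move together are not, so both p-values can overstate the evidence. With the flight groups exchanged all 12 would be called in opposite directions and 0 in the same. The 12 became 5 without control replicate 19, 6 without control replicate 22, 7 without suspension replicate 8 and 4 with the mean of a gene's probe sets. Bdh1 fell by 1.44 in flight and 1.38 in suspension, and Cyp2e1 rose by 1.56 and 1.10. Bdh1, Cyp2e1 and Gpt2 were also called between reloaded and control muscle, a comparison with the same control arrays. Across all 9133 genes the 2 effects had r = 0.259 and rho = 0.177, with the same sign in 55.2% (r = -0.259 with the flight groups exchanged), and among the other splits of the 8 flight arrays the largest r was 0.270 in size.

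**Figure D4:**
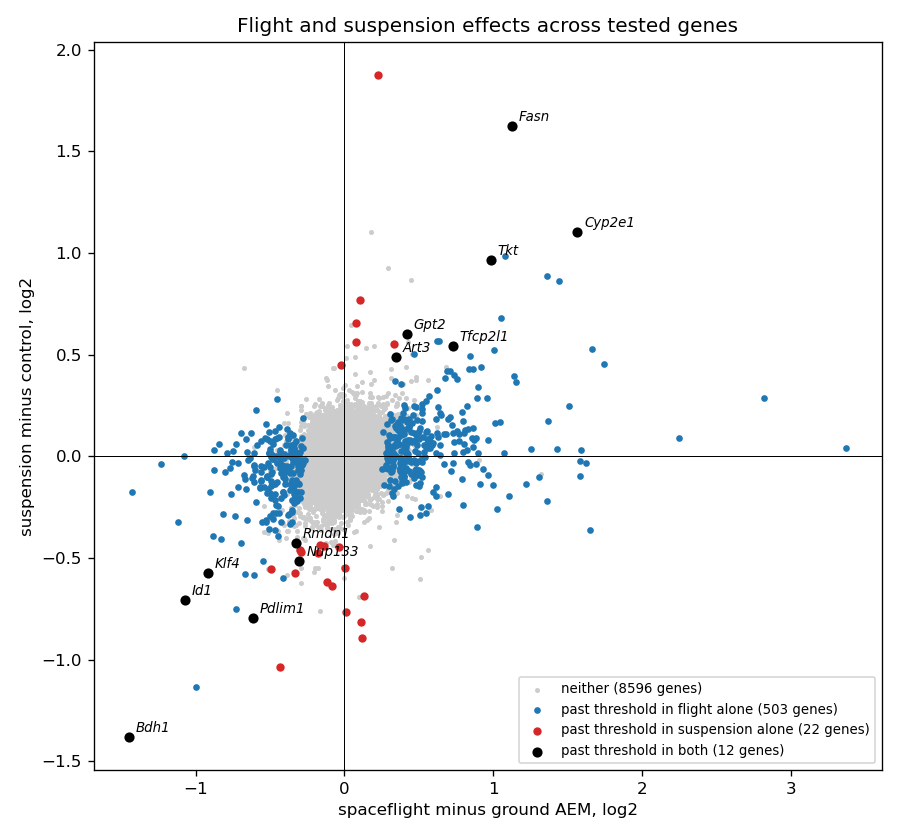
Log2 difference of each tested gene in spaceflight against ground AEM (horizontal) and in suspension against control (vertical), coloured by the comparisons in which it was called. The 12 genes called in both lie in the lower left and upper right, beside 503 called in flight and not in suspension and 22 called in suspension and not in flight.

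The difference between the flight and suspension effects itself passed for 116 genes, 79 with a higher and 37 with a lower value in flight. With the flight groups exchanged it passed for 529 genes, 259 higher and 270 lower, of which 80 are among the 116. The largest would then be Bdh1 (2.82) and, on the other side, Mt2 (-3.41), Ddit4 (-3.11), Fasn (-2.75) and Cyp2e1 (-2.67). The largest were Mt2 (3.33 ± 0.46, limma adjusted p = 0.000366), Ddit4 (2.54 ± 0.63, adjusted p = 0.0384), Mt1 (2.16), Btg2 (2.01) and the transcription factor Sox4 (1.68 ± 0.19, adjusted p = 2.31e-05). On the other side were Aplnr (-1.25), Sh3d19 (-1.08), the folliculin gene Flcn (-0.91), the RNA-binding protein gene Msi2 (-0.90) and Atp8a1 (-0.82, adjusted p = 0.0451). Camera with the preset correlation passed 14 of the 29 lists, 13 ranked as higher and 1 as lower in the flight effect. With an estimated correlation 2 of the 29 passed. The glucocorticoid list, 1 of these 2, differed as a group, with 7 of 16 members higher and 0 lower (9 adjusted over the list alone), a median of 0.70 and adjusted p = 0.0115 with an estimated correlation. Growth arrest and p53 targets did so too, with 3 of 11 higher (6 adjusted over the list alone), a median of 0.60 and the same adjusted p. With the flight groups exchanged the medians of these lists were -0.59 and -0.87, with camera adjusted p of 0.0225 and 0.0132 with an estimated correlation. Of 100 splits of the arrays into groups of these sizes, 5 had at least 116 genes. These splits mix the groups within both experiments and so remove both effects. They cannot decide whether chance accounts for a difference between the effects. The calls of Ddit4 and Atp8a1 ended when some single array was left out, and centring on the median of all probe sets gave 115 higher and 28 lower values. The flight and calf experiments also differ in the muscle named, ground control and array range, and a difference in scale does not cancel. The values here and in the next paragraph can therefore not be assigned to flight against unloading alone.

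Against the net effect of suspension and reloading, the flight effect differed for 250 genes, 147 higher and 103 lower, and with the flight groups exchanged for 336, of which 105 are among the 250. Mt2 (3.15), Ddit4 (2.96), Mt1 (2.18), Gadd45g (2.01) and Per1 (1.86 ± 0.27, limma adjusted p = 0.000124) were the largest positive differences. Hspa1b (-3.07 ± 0.37, adjusted p = 2.61e-05), Hspa1a (-2.64), Ppargc1a (-2.48 ± 0.38, adjusted p = 0.00017), Slc38a2 (-2.05) and the protease gene Adamts1 (-1.76) were the largest negative ones. With the flight groups exchanged the largest would be Bdh1 (2.47), Aplnr (1.58) and Sox18 (1.24). On the other side would be Mt2 (-3.59), Ddit4 (-2.68) and Atf3 (-2.49). Camera with the preset correlation passed 11 of the 29 lists, 5 ranked as higher and 6 as lower in the flight effect. With an estimated correlation 2 of the 29 passed. These were the glucocorticoid list (8 of 16 higher, 11 adjusted over the list alone) and growth arrest targets (4 of 11 higher, 6 adjusted over the list alone), each with adjusted p = 0.038. With the flight groups exchanged their medians were -0.64 and -0.75, each with camera adjusted p = 0.00489 with an estimated correlation. Of the genes that rose on reloading of suspended muscle, 7 were lower in flight (Ppargc1a, Slc38a2, Adamts1, Klf4, Pdlim1, Tpm4 and Clic4) against 1.23 expected (Fisher's exact test, two-sided, p = 0.000203). Another 7 were higher in flight (Jun, Btg2, Ier5, Ccn1, Hbegf, Midn and Sik1) against 1.59 expected (Fisher's exact p = 0.000937).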

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

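The second marker lists of adipocytes and Schwann cells were chosen after the first lists' results were seen, before the values of the second lists were. Single arrays far from the rest of their group were found in 18 of 300 gene and group pairs and 10 of 150 list and group pairs, while 0 of 20 measures of array quality had one; chance alone gives about 1 in 20.

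Ground AEM replicate 2 lay far from the other 3 arrays for Ddit4 (10.68 against a median of 7.57), Btg2 (9.96 against 8.68), Zfp36 (8.98 against 7.87), Adipoq (8.08 against 8.59) and Myh4 (13.49 against 13.28). It did so too for the glucocorticoid-responsive list (0.17 from the mean of its reference group against -0.10) and the unfolded protein response (-0.028 against 0.012). Ground AEM replicate 1 stood apart for Ucp3 (8.80 against 9.50) and Flcn (9.39 against 9.03), and replicate 3 for proteasome subunits (-0.061 against 0.016). Without ground AEM replicate 2, 470 genes were called in flight, where leaving out other single arrays gave between 283 (ground AEM replicate 3) and 491 (ground AEM replicate 1).

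Spaceflight replicate 10 stood apart for Cdkn1a (10.77 against 10.42) and Myh1 (12.32 against 12.46), replicate 9 for Pik3r1 (7.03 against 7.39), and replicate 8 for Psma4 (10.33 against 10.18) and the autophagy list (0.10 against 0.01). Spaceflight replicate 11 did so for Sln (7.42 against 8.53), Ube2j1 (8.75 against 8.83) and oxidative phosphorylation (-0.14 against -0.07). Suspension replicate 25 was far from the other 4 for Ddit4 (8.49 against 7.35) and the glucocorticoid-responsive list (0.38 against 0.03), in which it had the highest value of its group for 13 of 16 genes. Suspension replicate 11 stood apart for Ppargc1a (7.12 against 6.69) and suspension replicate 8 for Msi2 (6.73 against 7.08). Reloaded replicate 16 stood apart for Btg2 (7.92 against 8.88) and proteasome subunits (-0.22 against -0.01), and reloaded replicate 15 for endothelial markers (0.021 against -0.133). Control replicate 2 stood apart for Myh1 (12.23 against 12.45), fast fibre genes (-0.051 against 0.008) and stretch-responsive genes (0.18 against -0.05).

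The flight and suspension effects differed by the test of the difference for 116 genes, with Mt2 3.33, Ddit4 2.54, Mt1 2.16, Btg2 2.01, Sox4 1.68, Aplnr -1.25, Sh3d19 -1.08, Flcn -0.91, Msi2 -0.90 and Atp8a1 -0.82. With the flight groups exchanged, as the free-text descriptions have it, 529 genes differed. The flight effect and the effect of suspension plus reloading differed for 250 genes, with Mt2 3.15, Ddit4 2.96, Mt1 2.18, Gadd45g 2.01, Per1 1.86, Hspa1b -3.07, Hspa1a -2.64, Ppargc1a -2.48, Slc38a2 -2.05 and Adamts1 -1.76. In both differences, the muscle named, ground control and array range differ along with the treatment. Of 1235 probe sets with no symbol or several, which the comparisons of genes do not use, 72 passed the threshold in flight, 6 in suspension, 2 in reloaded against suspension and 2 in reloaded against control.

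Splitting the arrays into other groups of the same sizes tests whether chance gives as many called genes, the real grouping counted. In flight the real grouping called the most genes (1 of 35 splits, 515 genes against at most 0 in another). This is the smallest share that 35 splits can give, and it lies under 0.05 without adjustment over the comparisons. For the calf comparisons, the 100 splits are the real one and a random sample of the others. The real grouping called the most genes in reloaded against suspension (1 of 100, 53 against 43) and reloaded against control (1 of 100, 29 against 1). For suspension against control 4 of 100 splits had at least 34 genes, a share under 0.05 in this sample without adjustment, but the highest other split had 901. That split sets control replicates 19, 21 and 22 and suspension replicates 11 and 25 against control replicates 1 and 2 and suspension replicates 8, 9 and 30. The arrays thus divide across the 2 groups in more genes than suspension itself called. The division follows array range exactly, with 2.37 to 2.458 on the first side and 2.203 to 2.353 on the second, and the first component of the calf residuals had r = 0.92 with range. With array range as a covariate, added after seeing the data, 45 genes were called in suspension, 33 of them among the 34, so a linear trend with range does not account for those 33. What makes the range differ was not tested, and the labels give no batch. For the difference of flight and suspension effects, 5 of 100 splits had at least 116 genes and the highest other 231. For that of flight and suspension plus reloading, 1 of 100 had at least 250 and the highest other 214. These splits mix the groups within both experiments and so remove both effects, and they can hold the flight groups whole with the sign turned. They cannot decide whether chance accounts for a difference between the effects.

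Adipocyte markers were higher in spaceflight than in ground AEM arrays. Neither centring the arrays nor repeating the quantile step accounts for it, since the list's median was still 0.61 in the lower of its re-scaled runs. These steps had little to remove, because array medians in the flight experiment already lay between 6.15 and 6.23. More adipose tissue in the dissected flight muscle could account for it: the 11 members of a second adipocyte list above the level filter had a median of 0.36, and 14 of all 15 were higher. In that list Thrsp (1.36), Nnat (1.25), Plin4 (1.07) and Slc7a10 (0.55) passed, Pck1 (0.87) lies below the level filter (mean 4.25) and is not among the genes tested, while Aqp7 (-0.22) and, of the first list, Fabp4 (0.27) and Car3 (-0.11) did not. A response of muscle or fat cells to flight stays open and was not tested.

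Schwann cell markers were higher in suspension than in control arrays. Suspension replicate 8 alone does not account for it, as the median was 0.30 without that array. More nerve in the dissected muscle stays open: a second Schwann list had a median of 0.19 over its 11 members above the level filter, and 12 of 13 members were higher, but only Cnp (0.66, adjusted p = 0.0398) passed. The 2 lists therefore do not decide whether nerve was dissected along or nerve genes rose with unloading. The latter was not tested.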

How the results depend on the processing

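The exchange of the 2 flight groups, array range as a covariate, leaving out suspension replicates 8 and 9 together, centring on the median of all probe sets, quantile normalization over the tested genes, and the lists under other scaling or without suspension replicate 8 were chosen after the results were seen. The exchange was run for counts, the overlap, the correlation, and the genes and lists of the differences of effects. It is left out of the gene and list totals that follow. Over all other alternatives, 4210 values of named genes kept their direction and side of the threshold, 394 lost the call and 16 gained it. Another 55 uncalled ones changed sign and 0 called ones reversed. The 4210 include genes that were not called and so had no call to lose. Of the called named genes, leaving out some single array ended 18 of 55 calls in flight and 8 of 18 in suspension. It ended 4 of 19 in reloaded against suspension and 4 of 17 in reloaded against control. In list tests 288 values kept the call and 94 lost it: an estimated correlation kept 4 of 45 calls and fry 16. The direction of the test reversed in 1, proteasome subunits in reloaded against suspension without suspension replicates 8 and 9 (-0.0271), and that list's median also lay below 0 without replicate 8 (-0.0107) and with array range as a covariate (-0.0063). With the flight groups exchanged the correlation of the flight and suspension effects was -0.2591, the overlap 0 and flight minus suspension 529 genes, since the effects are then added. Every probe set on its own, which tests more features, gave 945 (flight), 56 (suspension), 86 (reloaded against suspension), 50 (reloaded against control), 234 (flight minus suspension) and 486 (flight minus reloading). An adjusted p under 0.01 left 181, 9, 17, 40 and 94 in flight, suspension, reloaded against control and both differences. A change of at least 1.5-fold left 153 in flight, 17 in suspension and 155 in flight minus reloading. The mean of probe sets gave 17 genes in suspension and an overlap of 4, and Foxo1, Ier5, Sln, Col5a2, Pdlim1 and Srxn1 each have at least 1 further probe set of opposite sign. Without suspension replicates 8 and 9, suspension had 7, reloaded against control 61 and the overlap 5. Array weights gave 88 in reloaded against control and 436 in flight minus reloading, the 2 groups alone 53 in reloaded against control, and array range as a covariate 318 in flight and 74 in reloaded against control. Leaving out each array in turn, which lowers the number of samples, gave 283 to 491 genes in flight, 15 to 47 in suspension, 39 to 63 in reloaded against suspension, 20 to 43 in reloaded against control, 78 to 157 and 181 to 298 for the differences, an overlap of 5 to 14, and a correlation of 0.177 to 0.295. Where the alternative's construction does not show it, the cause was not tested. No paired analysis was possible because the groups compared share no replicate numbers, and a floor for linear values was not run because the table is on the log2 scale. Signal near background limits genes such as Rrad (mean 5.17), below the filter at 5.83.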

Other observations

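For suspension replicate 8, the cell type test with the trend of deviation with gene level removed was chosen after the first result was seen, and so were the genes named in the next paragraph outside the naming rule.

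Antioxidant genes did not move together in flight. Beside Mt1 and Mt2, the plasma glutathione peroxidase Gpx3 rose by 0.48 ± 0.08 (SE, limma adjusted p = 0.00414), whereas the quinone reductase Nqo1 fell by 0.49 ± 0.09 (adjusted p = 0.00554). The other 12 members did not pass, among them Sod1 (0.17), Sod2 (-0.14) and Gclm (-0.33). The list of myogenic regulators also parted in flight: Myog and Musk, a receptor kinase of the neuromuscular junction, both also in the denervation list, rose, Id1 and Id3 fell, and the homeobox factor Six4 fell by 0.52 ± 0.12 (adjusted p = 0.0196), while Myod1 (-0.34) and Myf6 (-0.14) did not pass. Among clock genes that did not pass were Dbp (-0.45), Cry2 (0.62) and Nr1d2 (-0.30), so that Per1 and Nfil3 moved without Per2 (-0.07) and Per3 (-0.05).

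Suspension replicate 8 stands apart from the other calf arrays, with 0 genes over 1 log2 unit above and 16 over 1 unit below the mean of the other 4 suspension arrays. Another share of slow fibre muscle does not account for it, as slow fibre genes deviated by a median of -0.032, nor does a narrower range of signal as the whole cause, since its root mean square deviation was still 0.261 with the trend removed, against up to 0.204 on the other 14. More connective tissue, nerve, vessel or blood cells in the dissected piece cannot be told apart: skin and hair markers deviated by 0.432, which met the bound written beforehand, but they lie at low levels (mean 6.35) and low genes are high on that array. With that trend removed they deviated by 0.296, with Schwann cell markers at 0.256, adipocyte at 0.253, macrophage at 0.184, endothelial at 0.052 and tendon markers at -0.017. Biological explanations other than the make-up of the dissected piece were not tested.

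RNA breakdown was also looked at: the 3' minus 5' log2 signal of Gapdh on suspension replicate 8 was 0.0162, within -0.0765 to 0.0518 on the other 14 calf arrays, and that of Actb was -0.116, within -0.195 to 0.0442. The first component of the calf residuals held 34.4% of the variance, from -19.89 on suspension replicate 8 to 13.44 on suspension replicate 11. Across genes, the flight effect had r = 0.0911 with the effect of reloaded against control and r = -0.148 with that of reloaded against suspension.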
